A study of Arabidopsis thaliana with 9 samples.

How the data were processed

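RNA was sequenced from the roots of 9-day-old Arabidopsis thaliana seedlings grown on 1/2 MS medium. There were 3 genotypes with 3 libraries each: wild type (WT), a line that expresses a MYC-tagged ERF13 from the 35S promoter (35S:ERF13:MYC), and a line titled erf13-3. The labels of the last group conflict. The sample titles call it erf13-3, the genotype label calls it an SRDX line of ERF13, the headers of the deposited table for this line call it E13SRDX, and the series text writes the name without the 1 of ERF13. SRDX is a short repression domain that turns a transcription factor fused to it into a repressor. The title is used as the group's name below, and it says nothing about whether the line lacks ERF13. Per the labels' protocols, total RNA was isolated with a column kit, cDNA was primed with random primers, and the libraries were sequenced on an Illumina instrument. Nothing in the labels says whether the 3 libraries of a genotype came from separate plant pools or growth batches, so the p-values measure the spread between these libraries, which may be partly technical.

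For each library the authors deposited a table of genes with an expected count (an estimated count, not always whole) and an FPKM value, per the file headers. The aligner, the counting tool, the genome build and the strand setting are not given in the sources used here. Between 88.7% and 89.9% of a library's expected counts above 0 were whole within 0.005, and a table lists only genes with a value above 0, so a gene absent from a table was taken as 0. The authors also deposited a table for each line against WT, with mean FPKM, a log2 ratio of the means and a score called Probability, which is not a p-value. The smallest size of a log2 ratio in these tables was 1. How the authors' counting assigned reads shared by close paralogs is not stated, so values of near-identical copies (RBCS1B, RBCS2B and RBCS3B, LHCB1.1 to LHCB1.3, PHT1;1 and PHT1;2, MAM1 and MAM3) are uncertain, as are those of overlapping and antisense genes.

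Library totals ran from 12147128 to 12324144 expected counts, and 21952 to 22240 genes were listed per library. Depth therefore differed little between groups. A single gene, PYK10 (AT3G09260), took 1.38% to 2.35% of the counts. No 2 libraries of a genotype were duplicates: the chi-square per degree of freedom between their counts, expected to be near 1 for sampling noise, was 2.29 or more.

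Expected counts were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3. Genes were kept with filterByExpr (minimum count 10), which left 19714 of 24140 genes. TMM factors ran from 0.895 to 1.06. All 9 libraries entered a single quasi-likelihood fit with a mean per genotype and no covariate, so that the 3 comparisons share the estimate of the spread (6 residual degrees of freedom, common biological coefficient of variation 0.104). A gene was called at a Benjamini-Hochberg adjusted p under 0.05. All adjusted p-values of genes are from this edgeR test unless another tool is named. Standard errors (SE) of log2 fold changes are those implied by the F statistic, the size of the log2 fold change divided by the square root of F. FPKM values are the authors' and are given as mean ± SD of 3 libraries. Where a group had no count in any library, the fold is a lower bound against a floor of 3 counts per library. Where a group had 1 to 3 counts in all, the ratio of the summed counts is given with its exact 95% interval. Intervals and floors cover counting error only.

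The 26 gene lists (487 genes) were fixed before the data were examined. They cover ERF factors, very-long-chain fatty acid (VLCFA) elongation, suberin, Casparian strip, lignin, xylem, root hair, auxin, cell wall, cell cycle, nutrient, defence, abiotic stress and secondary metabolism genes, and green tissue genes as markers of shoot material. Each list was tested against all other genes with camera (limma 3.58.1) at its preset correlation between genes of 0.01, with adjustment over the 26 lists. Camera was then run again with the correlation estimated from the data. The lists were also tested with fry, which asks whether a list's genes move on balance in a single direction. Since fry does not compare a list with other genes, its call does not back a camera call. "Adjusted over the list alone" means that p-values were adjusted within a list's tested members. The genes named were set by a rule fixed at the same time: ERF13 and KCS16, the 6 largest rises and 6 largest falls per line (called, mean FPKM of at least 1, no overlap between the 3 libraries of the line and those of WT, with a symbol), the 3 called members with the smallest p of each list that had at least 3 called members or an adjusted list p under 0.05, and 5 genes called in opposite directions in both lines. A gene whose change is given outside this rule is said to be so. The values of 1 gene that the rule takes are not reported here.

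Gene symbols came from the fixed lists or from the RefSeq annotation of TAIR10.1, in which 23945 of the 24140 gene IDs had a record. Coordinates are from that annotation. The deposited tables print coordinates for 2547 genes with a record there, and all of them overlap the reference gene, with 70.2% identical in start and end.

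The labels do not say that equal replicate numbers belong together. Across genes, the deviations from the group means of same-numbered WT and erf13-3 libraries correlated at 0.18, 0.22 and 0.44. All lay above the bound of 0.1 set for taking the numbers as pairs. They are not separate support for pairing, since the deviations within a group sum to 0 and replicate 3 deviated most in both groups. WT replicate 1 correlated better with erf13-3 replicate 2 (0.27), and WT replicate 3 also correlated with 35S:ERF13:MYC replicate 1 (0.31). Same-numbered libraries correlated at -0.26, 0.09 and -0.2 for WT and 35S:ERF13:MYC, and at -0.06, 0.15 and -0.13 for 35S:ERF13:MYC and erf13-3. A fit on erf13-3 and WT alone with the replicate number as a block was added after this was seen.

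Both comparisons with WT use the same 3 WT libraries. Counts of all 9 libraries, WT included, were therefore simulated 20 times with no change between genotypes and each gene drawn independently. The overlap expected of independent lists was also computed. The gene and list tests were checked on simulated counts with the real means, library sizes and dispersions, in which 200 of 19714 genes were changed. In the simulated comparison of 35S:ERF13:MYC with WT, 39% of genes changed by 1.5-fold, 82% of genes changed by 2-fold and 98% of genes changed by 4-fold were recovered, with 12 false calls. For erf13-3 versus WT these shares were 51%, 78% and 98%, with 16 false calls. For erf13-3 versus 35S:ERF13:MYC they were 52%, 78% and 100%, with 9 false calls. In the first of these simulations the 12 false calls stood beside 26, 55 and 65 recovered genes. Only 200 genes were changed there, while 27.3% to 38.7% of the tested genes were called in the data. The adjusted threshold was therefore stricter in the simulation, and these shares do not give the power of the real comparisons. The list whose genes were raised was called in each simulation, and of 25 unchanged lists 0, 0 and 1 were called in these comparisons. These lists held random genes drawn independently of each other. The list check therefore does not cover lists whose genes move together, where estimated correlations reached 0.86.

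Alternatives fixed before the data were examined were DESeq2 size factors in edgeR, DESeq2 1.42.0 with its Wald test, limma-trend on log2(FPKM + 1) and on log2(FPKM + 0.1), no filter beyond 1 count in any library, a mean FPKM of at least 1, the replicate number as a block, fits on the 2 genotypes compared, leaving out each library in turn, an adjusted p under 0.01, and a change of at least 2-fold. Leaving out 3 libraries together, and the block in a fit on erf13-3 and WT alone, were added after seeing the data.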

Results

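Gene expression was measured by RNA-seq in roots of 9-day-old seedlings of WT, 35S:ERF13:MYC and erf13-3, with 3 libraries each and 12147128 to 12324144 expected counts per library. ERF13 (AT2G44840, chromosome 2, 18495215 to 18496327 in TAIR10.1) encodes an ethylene response factor of the AP2/ERF family. KCS16 (AT4G34250, chromosome 4, 16394600 to 16396703) encodes a 3-ketoacyl-CoA synthase, the class of enzyme that sets the chain length in VLCFA elongation. The libraries fell apart by genotype on the first pair of principal components of log2 CPM, which held 58.5% and 23.1% of the variance. The third held 7.05% and separated WT replicate 3, 35S:ERF13:MYC replicate 1 and erf13-3 replicate 3 from the other libraries of their groups.

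ERF13 transcript was scarce in WT, at 1.08 ± 0.151 FPKM (SD, n = 3), and far higher in both lines. It reached 822 ± 72 FPKM in 35S:ERF13:MYC, a log2 fold change of 9.45 (SE 0.18, adjusted p = 4.7e-11), and 2780 ± 233 FPKM in the libraries labelled erf13-3, a log2 fold change of 11.19 (SE 0.19, adjusted p = 9.4e-12). The counts do not tell transgene from endogenous transcript. All 3 libraries titled erf13-3 thus held more ERF13 transcript than any WT library, and a direction given for this line below is not that of a line that lacks the transcript. KCS16 moved in opposite directions, from 1.47 ± 0.197 FPKM in WT down to 0.477 ± 0.146 in 35S:ERF13:MYC (log2 fold change -1.73, SE 0.24, adjusted p = 0.00024) and up to 4.03 ± 0.357 in erf13-3 (log2 fold change 1.31, SE 0.18, adjusted p = 0.00017).

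**Figure D1:**
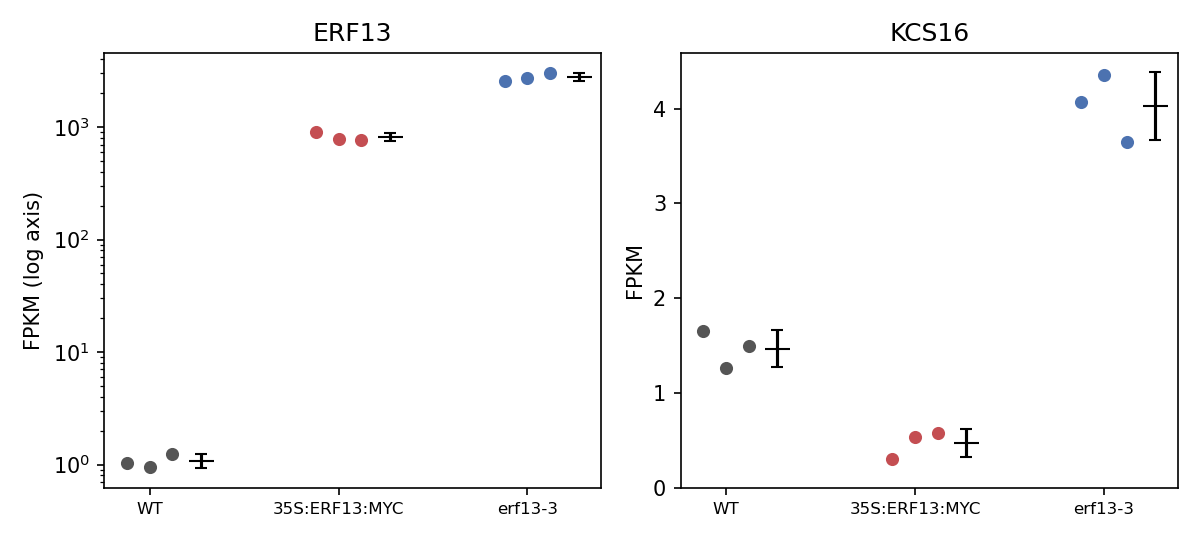
FPKM of ERF13 (left, log axis) and KCS16 (right, linear axis) in each library of the 3 genotypes, with points for libraries and a bar for the mean ± SD of 3. ERF13 lies near 1.08 FPKM in WT and at 822 and 2780 FPKM in the lines, while KCS16 is lowest in 35S:ERF13:MYC and highest in erf13-3.

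The first comparison asked which root genes change when ERF13 is overexpressed. In 35S:ERF13:MYC roots 7 of 7 tested genes of the thalianol and marneral triterpene clusters, 10 of 10 Casparian strip, 12 of 17 suberin and 15 of 19 aquaporin genes fell, and 6 of 8 aliphatic glucosinolate genes rose. These lists were called at the preset correlation between genes. With an estimated correlation no list was called, and the 10 lists called at the preset had an adjusted p of 0.15 to 0.73. Of 19714 genes tested, 6209 were called, 2713 higher and 3496 lower, and 420 and 1009 of these changed by at least 2-fold. Apart from ERF13, the largest rises were in CCOAMT, a caffeoyl-CoA O-methyltransferase gene, with a ratio of 111 (95% counting interval 37.7 to 541) on 3 WT counts, CYP81F2, which modifies indole glucosinolates (log2 fold change 6.09), BGLU32 (5.88), CYP706A1 (4.72) and SQE6, a squalene epoxidase gene (4.62). Among the largest falls were the transcription factor gene NAC074, with a WT-to-line ratio of 255 (87 to 1240) on 3 counts in the line, the phosphate transporter gene PHT1;8, with 150 (26.5 to 5970) on 1 count, and CYP71B3, with 72.9 (12.6 to 2920) on 1 count. PYL3, an abscisic acid receptor gene, was at least 4.09-fold lower and FMO1, a gene of systemic defence, at least 2.88-fold lower, since neither had a count in the line. PEPC1, a phosphatase gene of the phosphate starvation response, had a log2 fold change of -6.88 (SE 1.35), from 17.1 ± 22.7 FPKM in WT. Its WT level was carried by replicate 3, with 661 counts against 59 and 62, and without that library the log2 fold change was -4.7.

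All 7 tested members of the root triterpene clusters fell (adjusted p = 1.5e-22; adjusted p = 0.15 with an estimated correlation). The marneral synthase gene MRN1 had a log2 fold change of -4.23 and stood at 14.3 ± 0.869 FPKM in the line, CYP705A12 had a log2 fold change of -3.16, and the thalianol synthase gene THAS1 one of -1.53. All 10 Casparian strip genes fell (adjusted p = 7.9e-08; 0.49 as the adjusted p with an estimated correlation). They included CASP5 (log2 fold change -1.13), which encodes a scaffold protein of the strip, and the peroxidase gene PER64 (-1.06). Of 17 suberin genes 12 fell and none rose (adjusted p = 1.6e-06 for the list and 0.49 with an estimated correlation), with GPAT5 (-1.16), the transporter gene ABCG6 (-1.04) and the regulator gene MYB93 (-0.79) the best supported. In the root hair list 10 of 17 fell (adjusted p = 0.0032; adjusted p = 0.63 with an estimated correlation), among them PRP1 (-1.16), RSL2 (-1.04) and XTH26 (-1.32). Of 12 xylem secondary wall genes 5 were called lower, with log2 fold changes of -0.35 for CESA4, -0.32 for CESA7 and -0.54 for MYB46, and the list was not called (adjusted p = 0.13). Each of these 3 calls was lost without single libraries, with adjusted p up to 0.065 for CESA4 and 0.1 for CESA7, both without 35S:ERF13:MYC replicate 2, and up to 0.13 for MYB46 without WT replicate 2.

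Of 19 aquaporin genes 15 fell (adjusted p = 9.4e-07; adjusted p = 0.63 with an estimated correlation), with PIP1;5 at 114 ± 1.66 against 246 ± 24.6 FPKM (log2 fold change -1.22), TIP2;3 at -1.49 and TIP2;2 at -1.2. In the phosphate starvation list 14 of 18 fell and none rose (adjusted p = 8e-04; adjusted p = 0.73 with an estimated correlation). Examples were the sulfolipid synthase gene SQD2 (-1.91, SE 0.34) and the transporter gene PHT1;1 (-1.53, SE 0.28). WT replicate 3 stood apart here. Its mean over the list was 1.27 above the WT mean on the log2 scale, against -0.61 and -0.66 for the other WT libraries, and without it the list's median log2 fold change went from -1.52 to -0.77, with 11 members called lower. The list was not called by fry (adjusted p = 0.096). Iron deficiency genes split, with 10 higher and 7 lower of 21 (adjusted p = 0.65), and the falls included their regulator FIT (-1.3), NAS1 (-1.81) and CYP82C4 (-3.54). In the nitrate list 4 of 9 fell (adjusted p = 0.13), NIA1 (-0.83), NRT3.1 (-0.88) and LBD38 (-0.52) among them, and the LBD38 call was lost without 35S:ERF13:MYC replicate 2 (adjusted p = 0.059).

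Of 8 aliphatic glucosinolate genes 6 rose and none fell (adjusted p = 8.7e-07; adjusted p = 0.49 with an estimated correlation), led by the chain elongation genes MAM3 (log2 fold change 1.62) and MAM1 (1.17) and by CYP83A1 (1.78). In the indole glucosinolate and camalexin list 7 of 11 rose (adjusted p = 0.00074; adjusted p = 0.63 with an estimated correlation), including ASA1 (1.09), GSTF6 (1.29) and CYP71B15 (1.18). Of 29 green tissue genes 19 fell and none rose (adjusted p = 7.9e-08; 0.63 as the adjusted p with an estimated correlation). RBCS1A, for a Rubisco small subunit, went from 103 ± 6.69 to 27.3 ± 9.91 FPKM, RCA had a log2 fold change of -1.08 and LHCA3 one of -1.09. The libraries of the line differed in this list, with means of 0.02, -0.52 and -1.46 relative to the WT mean on the log2 scale for replicates 1 to 3, against -0.44, 0.33 and 0.1 in WT, so replicate 1 lay within the WT range. In the abscisic acid and cold list 12 of 21 fell and 2 rose (adjusted p = 0.0024; adjusted p = 0.49 with an estimated correlation), with NCED3, for a rate-limiting step of abscisic acid synthesis, at -1.35, ABI1 at -0.67 and ERD10 at -0.71.

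The VLCFA elongation list was not called as a whole (adjusted p = 0.1), with 11 lower and 3 higher of 19. The members with the smallest p were KCS3 (2.15), KCS2 (-0.69) and KCS5 (-0.92). It was called in the limma fits on FPKM (adjusted p = 0.00052 and 0.00047), among genes with a mean FPKM of at least 1 (0.012) and without WT replicate 2 (0.037). Auxin genes, 8 higher and 6 lower of 36 (adjusted p = 0.29), included the conjugating enzyme genes GH3.3 (2.75) and GH3.6 (-0.91) and the repressor gene IAA28 (-0.61). Cell wall loosening genes were 5 higher and 12 lower of 23 (adjusted p = 0.1), with XTH20 at 2.26, XTH18 at -1.25 and XTH23 at -1.23. Of 17 ERF genes 4 fell and 1 rose (adjusted p = 0.26), the falls including ERF108 (-1.35), ERF113 (-0.83) and ERF1A (-1.21). No list call was made for defence genes. The early pattern-triggered list had 5 higher and 5 lower of 17 (adjusted p = 0.52), with CYP81F2 at 6.09, NHL10 at -4.1 and WRKY29 at -2.28, and its median of -0.11 differs in sign from the test. Jasmonate and ethylene defence genes were 2 higher and 5 lower of 20 (adjusted p = 0.25), with VSP2 at -1.91, JAZ3 at -0.91 and JAZ6 at 1.27. Salicylate genes were 1 higher and 3 lower of 11 (adjusted p = 0.73), with WRKY54 at 2.39 and WRKY70 at -1.38.

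Phenylpropanoid and lignin genes were 2 higher and 7 lower of 18 (adjusted p = 0.14), including PAL4 (-0.81), LAC11 (-0.61) and F5H1 (0.98). Hypoxia genes were 2 higher and 6 lower of 13 (adjusted p = 0.13), with SUS1 at -0.92, ACO1 at 0.89 and PDC1 at -1. Clock genes were 1 higher and 5 lower of 15 (adjusted p = 0.14), with LUX at -0.51, ELF4 at -1.24 and PRR5 at -0.98. Of 9 flavonoid genes 3 rose (adjusted p = 0.14), UGT78D1 (1.17), chalcone synthase CHS (0.45) and CYP75B1 (0.7), the last of which was lost without WT replicate 2 (adjusted p = 0.06). Of 23 cell cycle genes 3 were called higher (adjusted p = 0.13). They were CDC20.1 (0.4), MCM5 (0.39) and PCNA1 (0.37), and each call was lost in 4 or 5 of the 9 fits that left out 1 library, with adjusted p up to 0.1 without WT replicate 3, 0.1 without 35S:ERF13:MYC replicate 2 and 0.14 without WT replicate 2. In the heat shock list 1 of 13 fell (adjusted p = 0.98), HSFA7A (-0.72), which was named after its value was seen.

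Some lists not called here were called elsewhere. The xylem list (adjusted p = 0.024 and 0.021) and the cell wall loosening list (0.037 and 0.039) were called in the limma fits on FPKM. Without WT replicate 1, both had an adjusted p of 0.038, as had the cell cycle list, and the phenylpropanoid and lignin list one of 0.05. Without 35S:ERF13:MYC replicate 1 the cell cycle list had an adjusted p of 0.048. Some counts depended on WT replicate 3. Without it, higher and lower members were 4 and 3 for ERF, 6 and 3 for early pattern-triggered, 4 and 5 for jasmonate and ethylene defence, 2 and 3 for salicylate, 1 and 4 for hypoxia, 1 and 1 for heat shock and 0 and 7 for clock genes, with 2 xylem genes lower and no cell cycle gene called.

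Adjusted over the list alone, the counts of higher and lower members were 10 and 6 for auxin, 5 and 13 for cell wall loosening, 2 and 5 for the clock, 6 and 5 for early pattern-triggered, 2 and 4 for ERF, 11 and 7 for iron deficiency and 3 and 13 for VLCFA elongation genes. The lower members were then 20 for green tissue, 15 for phosphate starvation, 12 for root hair, 14 for suberin and 8 for xylem genes, and no cell cycle or heat shock gene was called. The other 12 lists had the same counts as over all genes.

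The edgeR count of 6209 fell to 3903 without 35S:ERF13:MYC replicate 2. In the limma fits on FPKM with no TMM scaling, the median log2 fold change over all genes was 0.12 or 0.13 against 0.02, and the share of higher calls was 60% against 44%. These fits also changed the test and the genes tested, and with DESeq2 size factors in edgeR the share was 42%. In the authors' deposited table for this line, 1305 genes are listed, of which 1239 were tested here and 1192 were called in the same direction, with 0 called in the opposite direction and 47 not called. It lists 527 genes as up and 778 as down, and leaves out 318 of the 1429 genes called here with a change of at least 2-fold.

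**Figure D2:**
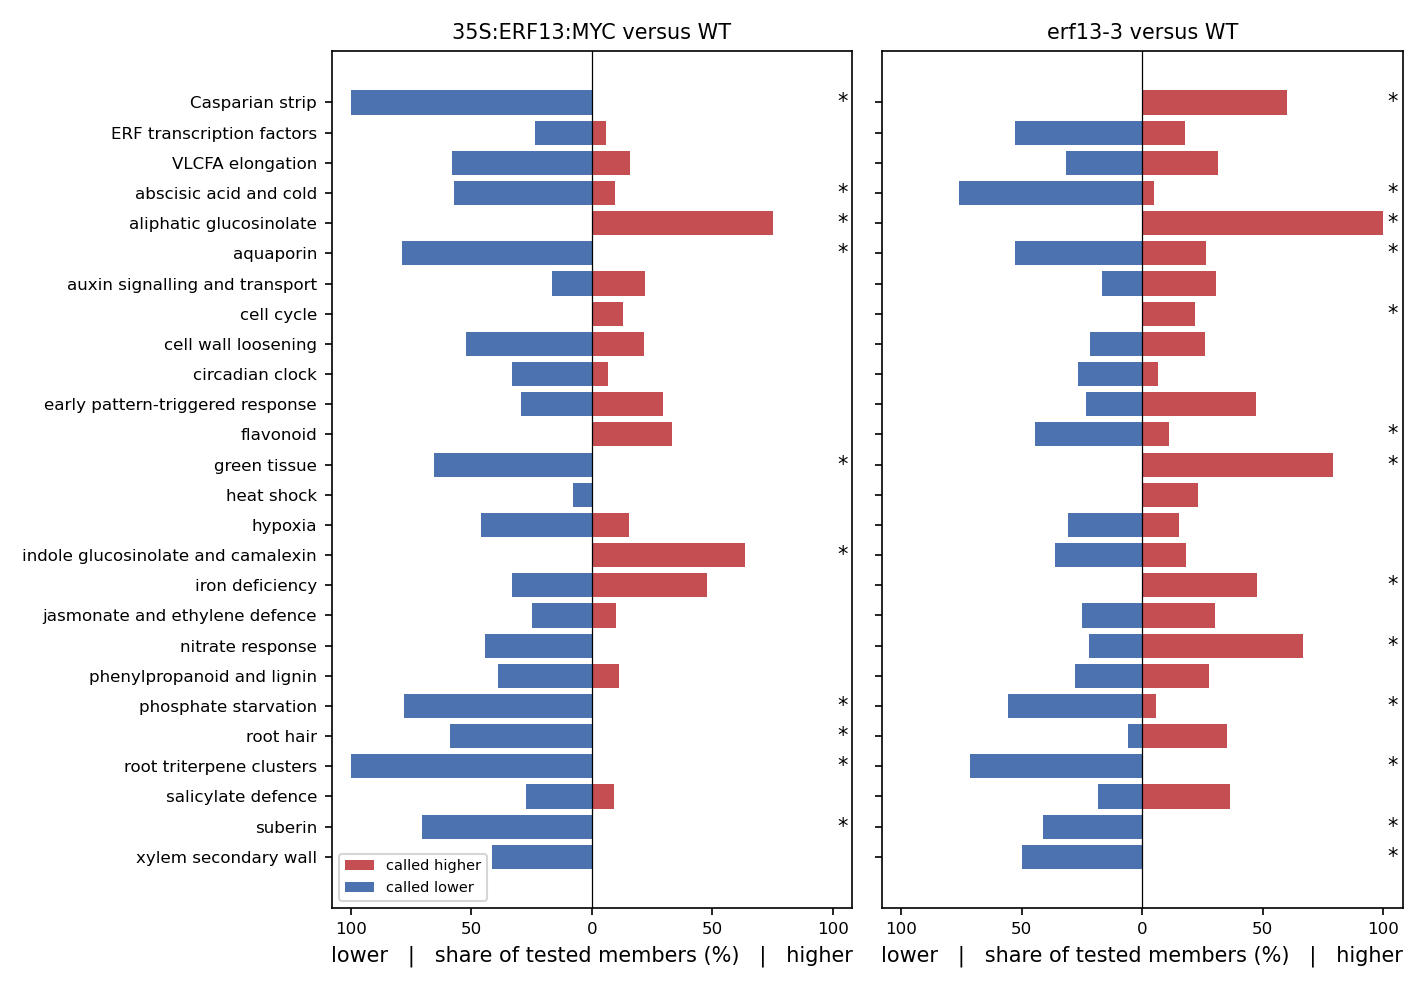
Share of the tested members of each of the 26 fixed gene lists called higher (right of 0) or lower (left of 0) in each line against WT, with an asterisk where the list had an adjusted p under 0.05 at the preset correlation. All 10 Casparian strip genes are lower in 35S:ERF13:MYC and 6 are higher in erf13-3, while triterpene cluster genes are lower in both.

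The second comparison asked the same of erf13-3. In this line 5 of 7 triterpene cluster and 16 of 21 abscisic acid and cold genes fell, and 23 of 29 green tissue, 10 of 21 iron deficiency and 8 of 8 aliphatic glucosinolate genes rose. These lists were called at the preset correlation. With an estimated correlation no list was called, and the 13 lists called at the preset had an adjusted p of 0.056 to 0.63. Here 5381 genes were called, 2689 higher and 2692 lower, and 770 and 833 of these changed by at least 2-fold. After ERF13, the largest rises were in CCOAMT, with a ratio of 38.3 (12.8 to 188) on 3 WT counts, LCR37, a defensin-like gene, with 38 (12.7 to 187) on 3 WT counts, the zinc finger gene ZFP10 (log2 fold change 5.04), the flagellin receptor gene FLS2 (5.03) and BGLU28 (4.88). The largest falls were in CER4, a fatty acyl-CoA reductase gene that makes primary alcohols (-6.72, from 7.9 ± 1.96 to 0.08 ± 0.052 FPKM), in MRN1 (-6.34) and IGMT1, an indole glucosinolate methyltransferase gene (-5.3), and in NAC042, RAP2.9 and MIF2. For these last genes the WT-to-line ratios were 77.3 (13.4 to 3090) on 1 count, 57.7 (9.91 to 2320) on 1 count and 35.6 (11.8 to 175) on 3 counts.

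Of 7 triterpene cluster genes 5 fell and none rose (adjusted p = 1.2e-19; adjusted p = 0.063 with an estimated correlation). MRN1 stood at 3.36 ± 0.418 FPKM in the line (log2 fold change -6.34), CYP71A16 had a log2 fold change of -1.48 and THAH one of -1.33. In the abscisic acid and cold list 16 of 21 fell and 1 rose (adjusted p = 6.4e-14; adjusted p = 0.056 with an estimated correlation), with the desiccation marker genes RD29B (-3.83) and RD29A (-2.74) and the dehydrin gene LTI30 (-1.96). Of 9 flavonoid genes 4 fell and 1 rose (adjusted p = 0.0051; adjusted p = 0.63 with an estimated correlation), CYP75B1 (-2.49), F3H (-1.07) and CHS (-0.83) among the falls. Aquaporin genes were 10 lower and 5 higher of 19 (adjusted p = 5.9e-05; adjusted p = 0.63 with an estimated correlation), with PIP1;1 at 195 ± 28.4 against 844 ± 49 FPKM (-2.25), TIP2;2 at -2.18 and PIP2;3 at -1.44.

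Iron deficiency genes rose in 10 of 21 and fell in none (adjusted p = 3.2e-06; adjusted p = 0.056 with an estimated correlation). FIT went from 14.2 ± 0.231 to 43.1 ± 3.49 FPKM (1.48), and CYP82C4 (2.41) and F6'H1 (1.58), for steps of iron-mobilising coumarin synthesis, rose with it. All 8 aliphatic glucosinolate genes rose (adjusted p = 9.2e-06; adjusted p = 0.59 with an estimated correlation), including MAM1 (1.27), MAM3 (0.92) and CYP83A1 (1.39). In the indole glucosinolate and camalexin list 2 rose and 4 fell of 11 (adjusted p = 0.096), with CYP71B15 at -2.22 and GSTF6 at 0.94. Of 29 green tissue genes 23 rose and none fell (adjusted p = 8e-11; 0.63 as the adjusted p with an estimated correlation), such as LHCB2.1 (1.81), PSAF (0.94) and GAPB (1.53). In the nitrate list 6 of 9 rose and 2 fell, with the nitrate reductase gene NIA1 at 168 ± 20.5 against 29.6 ± 4.89 FPKM (2.37), the nitrite reductase gene NIR1 at 1.07 and HRS1 at -1.45. This list's adjusted p of 0.025 rose to 0.63 with an estimated correlation, to 0.14 and 0.15 in the limma fits on FPKM, and to 0.095 without WT replicate 1, 0.051 without WT replicate 2 and 0.11 without erf13-3 replicate 3. It was 0.056 with fry.

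Casparian strip genes rose in 6 of 10 and fell in none (adjusted p = 0.014; adjusted p = 0.63 with an estimated correlation), by 0.54 for the regulator MYB36, 0.54 for CASP5 and 0.67 for the kinase gene SGN1 on the log2 scale. Suberin genes fell in 7 of 17 and rose in none (adjusted p = 0.034; adjusted p = 0.63 with an estimated correlation), among them GPAT7 (-1.17), FAR1 (-1.71) and ABCG6 (-0.47). The suberin call was lost without WT replicate 3 (adjusted p = 0.093), without erf13-3 replicate 2 (0.053) and in the limma fits (0.056 and 0.053). Xylem secondary wall genes fell in 6 of 12 (adjusted p = 0.025; adjusted p = 0.63 with an estimated correlation), with MYB46 at -0.76, CESA8 at -0.39 and CESA4 at -0.41, and this list's call too was lost without WT replicate 3 (adjusted p = 0.093). In the phosphate starvation list 10 of 18 fell and 1 rose (adjusted p = 0.025; adjusted p = 0.63 with an estimated correlation), including PHO1;H1 (-0.82), PAP17 (-1.2) and the noncoding RNA gene AT4 (-1.25). Without WT replicate 3, the library with the highest values of this list, its adjusted p was 0.12 and its median log2 fold change went from -1.13 to -0.3, and fry did not call the list (adjusted p = 0.2). Cell cycle genes rose in 5 of 23 (adjusted p = 0.025; adjusted p = 0.63 with an estimated correlation), with CDC20.1 at 0.65, AUR1 at 0.5 and CYCB1;4 at 0.47, and without WT replicate 3 the list was not called (adjusted p = 0.12).

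VLCFA elongation genes were 6 higher and 6 lower of 19 (adjusted p = 0.68), KCS3 falling (-2.01) along with KCS2 (-0.71). Root hair genes were 6 higher and 1 lower of 17 (adjusted p = 0.093), with RSL2 at -2.28, RSL4 at 0.86 and XTH26 at 1.23. Auxin genes were 11 higher and 6 lower of 36 (adjusted p = 0.14), among them GH3.3 (2.93), the influx carrier gene LAX1 (-1.99) and GH3.6 (0.99). ERF genes were 3 higher and 9 lower of 17 (adjusted p = 0.096), with ERF108 at -1.34, ERF4 at -1.36 and ERF2 at 3.14. Early pattern-triggered genes were 8 higher and 4 lower of 17 (adjusted p = 0.096), WRKY53 (1.73), FRK1 (3.64) and NHL10 (-2.7) having the smallest p. Jasmonate and ethylene defence genes were 6 higher and 5 lower of 20 (adjusted p = 0.87), with the chitinase gene PR3 at -4.64, PR4 at -1.92 and AOC3 at 1.01. Salicylate genes were 4 higher and 2 lower of 11 (adjusted p = 0.68), with FMO1 at 2.96, ICS1 at -1.19 and NPR1 at -0.52. The list's median of -0.13 differs in sign from its mean and test, but was 0.07 without WT replicate 3.

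The other lists were not called. Phenylpropanoid and lignin genes were 5 higher and 5 lower of 18 (adjusted p = 0.71), with CAD5 at -1.41, PRX72 at 0.57 and LAC17 at -0.63. Cell wall loosening genes were 6 higher and 5 lower of 23 (adjusted p = 0.71), with EXPA17 at -0.8, EXPA11 at 0.78 and XTH12 at 1.07. Hypoxia genes were 2 higher and 4 lower of 13 (adjusted p = 0.27), with SUS1 at -0.98, ETR2 at 0.99 and LBD41 at -1.2. Clock genes were 1 higher and 4 lower of 15 (adjusted p = 0.12), with RVE1 at -1.26, LHY at -0.74 and LNK2 at -0.57. Of 13 heat shock genes 3 were called higher (adjusted p = 0.13), HSP17.8 (0.55), ROF2 (0.4) and HSP70 (0.31). The ROF2 and HSP70 calls were lost without single libraries, with adjusted p up to 0.081 without erf13-3 replicate 2 and up to 0.16 without erf13-3 replicate 1.

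Some of these lists too were called elsewhere. The root hair list was called in the limma fits on FPKM (adjusted p = 0.036 and 0.044) and without erf13-3 replicate 1 (0.011). With the replicate number as a block it was called in the fit on all libraries (adjusted p = 0.029) and in the fit on erf13-3 and WT alone (0.026), and the latter also called the indole glucosinolate and camalexin list (0.048). This last list was also called without WT replicate 1 (0.046), without erf13-3 replicate 3 (0.0045) and among genes with a mean FPKM of at least 1 (0.029). Without WT replicate 3 the clock list had an adjusted p of 0.039 and the early pattern-triggered list one of 0.033, without erf13-3 replicate 1 the clock list one of 0.041, and without WT replicate 1 the ERF list one of 0.041. In the fit on erf13-3 and WT alone with no block, the early pattern-triggered list had an adjusted p of 0.042. Without WT replicate 3, higher and lower members of this comparison were 9 and 10 for aquaporin, 7 and 6 for ERF, 3 and 8 for phosphate starvation and 1 and 6 for suberin genes, with 9 Casparian strip and 5 heat shock genes higher, and the suberin list's median log2 fold change went from -0.09 to 0.01.

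Adjusted over the list alone, higher and lower members of the second comparison were 1 and 17 for abscisic acid and cold, 12 and 6 for auxin, 7 and 6 for cell wall loosening, 4 and 9 for ERF, 1 and 5 for flavonoid, 2 and 5 for hypoxia, 5 and 7 for phenylpropanoid and lignin, 1 and 11 for phosphate starvation and 7 and 1 for root hair genes. There were then 26 green tissue genes higher and 7 xylem genes lower, and the other 15 lists had the same counts as over all genes. The median of the cell wall loosening list (-0.05) and the mean of the jasmonate and ethylene defence list (-0.09) differ in sign from their tests. Without WT replicate 3 that median was 0.03.

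In the limma fits on FPKM, the median log2 fold change over all genes for this line was 0.13 or 0.15 against 0.02, and the share of higher calls was 71% against 50%. The authors' deposited table for this line lists 1656 genes, of which 1569 were tested here and 1499 were called in the same direction, with 0 called in the opposite direction and 70 not called. It lists more genes as up (989) than down (667), unlike the 770 higher and 833 lower called here at 2-fold, and leaves out 276 of these 1603.

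**Figure D3:**
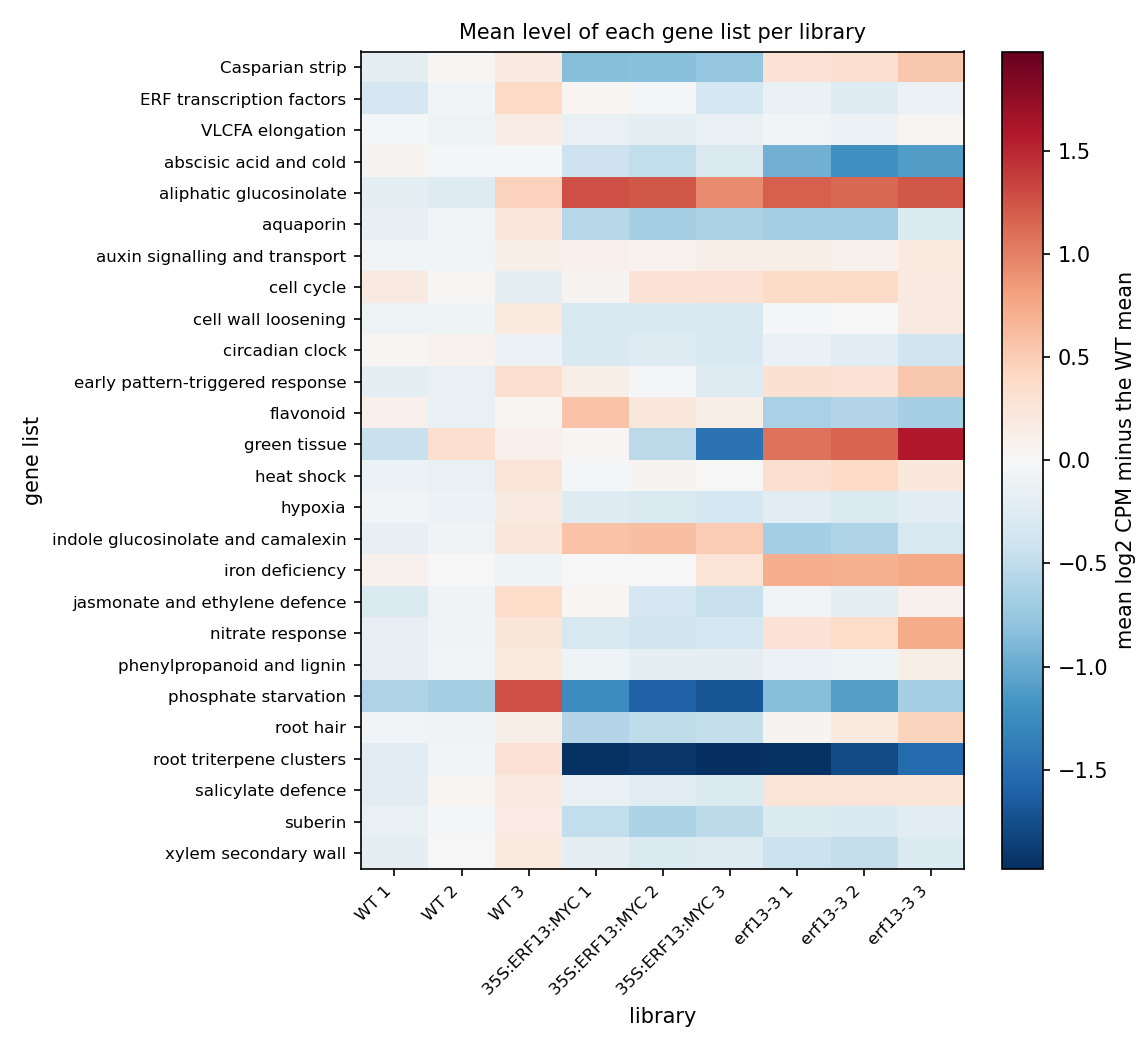
Mean log2 CPM of each gene list in each library, minus the list's WT mean, as a colour scale from low (blue) to high (red). The phosphate starvation list stands at 1.27 in WT replicate 3 and at -0.61 and -0.66 in the other WT libraries.

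The third comparison set both lines against each other. In the direct test 7626 genes differed, 4156 higher and 3470 lower in erf13-3 than in 35S:ERF13:MYC. Green tissue genes were higher in erf13-3 in 23 of 29 (adjusted p = 4.4e-19; adjusted p = 0.45 with an estimated correlation), Casparian strip genes in 10 of 10 (adjusted p = 9.6e-10; adjusted p = 0.45 with an estimated correlation) and root hair genes in 13 of 17, with 1 lower (adjusted p = 6e-04; adjusted p = 0.45 with an estimated correlation). Nitrate genes were 6 higher and 1 lower of 9 (adjusted p = 0.0057; adjusted p = 0.89 with an estimated correlation). Abscisic acid and cold genes were 12 lower and 2 higher of 21 (adjusted p = 0.0018; adjusted p = 0.45 with an estimated correlation), indole glucosinolate and camalexin genes 8 lower and 1 higher of 11 (adjusted p = 2e-04; adjusted p = 0.45 with an estimated correlation), and flavonoid genes 4 lower of 9 (adjusted p = 0.0013; adjusted p = 0.45 with an estimated correlation). For the iron deficiency list (adjusted p = 0.0066 for higher; adjusted p = 0.45 with an estimated correlation) the median of -0.24 and the mean of 0.58 differed in sign, with 8 higher and 10 lower of 21, and the limma fits did not call it (adjusted p = 0.26 and 0.34). Adjusted over the list alone, green tissue had 24 higher and abscisic acid and cold 13 lower members, and the other 6 lists the same counts.

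Genes called in both lines numbered 2506, of which 1489 changed in the same direction and 1017 in opposite directions. With a 2-fold change required, the numbers were close, with 218 in the same and 232 in opposite directions, and their difference was not tested. There were 963 genes lower in both lines, against 477 for independent lists of these sizes, and 526 higher in both, against 370. Opposite changes were 626 genes lower in 35S:ERF13:MYC and higher in erf13-3, against 477, and 391 the other way, against 370. With all 9 libraries simulated and no gene changed, at most 1 gene was called in both. With no gene changed, few calls can pass the adjusted threshold at all. The simulation thus cannot show how far the shared WT libraries raise the overlap. The WT group is too small to be split into parts of at least 2 libraries. Part of the excess of like changes may therefore come from the shared WT libraries, whose noise pushes both fold changes the same way. Opposite changes also exceeded the values for independent lists. Those values take every gene as equally likely to be called, which genes of unlike counts and spread are not. They are thus no null level for the overlap. Without WT replicate 2 the count called in both was 1663, of which 969 changed in the same direction.

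Across genes, which are not independent replicates, the log2 fold changes of both lines had a Pearson correlation of 0.045. Leaving out 1 library gave 0.026 to 0.13, and limma on FPKM 0.11 and 0.08. Simulated unchanged groups that shared simulated WT libraries gave a correlation of 0.507. The covariance of the fold changes was 0.021, against 0.0203 in the simulation, a difference of 0.001. Leaving out ERF13, the correlation was 0.0343 and the covariance 0.016, which is -0.0043 relative to the simulation. Including low-count genes, the correlation was 0.23.

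The 5 genes with the best joint support for opposite changes were RBOHB, FIT, UGT73B5, LOX1 and LTP5. RBOHB, for an NADPH oxidase, stood at 6.18 ± 0.754 FPKM in WT, 16 ± 0.361 in 35S:ERF13:MYC and 0.677 ± 0.095 in erf13-3, a direct log2 difference of -4.58 (SE 0.13, adjusted p = 1.4e-09). FIT fell by 1.3 in 35S:ERF13:MYC and rose by 1.48 in erf13-3 on the log2 scale. UGT73B5, a glucosyltransferase gene, rose by 1.12 in the overexpressor and fell by 1.35 in erf13-3, and the lipoxygenase gene LOX1 rose by 0.99 and fell by 1.55. The lipid transfer protein gene LTP5 went from 5.49 ± 1.01 FPKM in WT to 0.847 ± 0.17 and 24.2 ± 0.774, a direct log2 difference of 4.8 (SE 0.18, adjusted p = 4.6e-09).

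**Figure D4:**
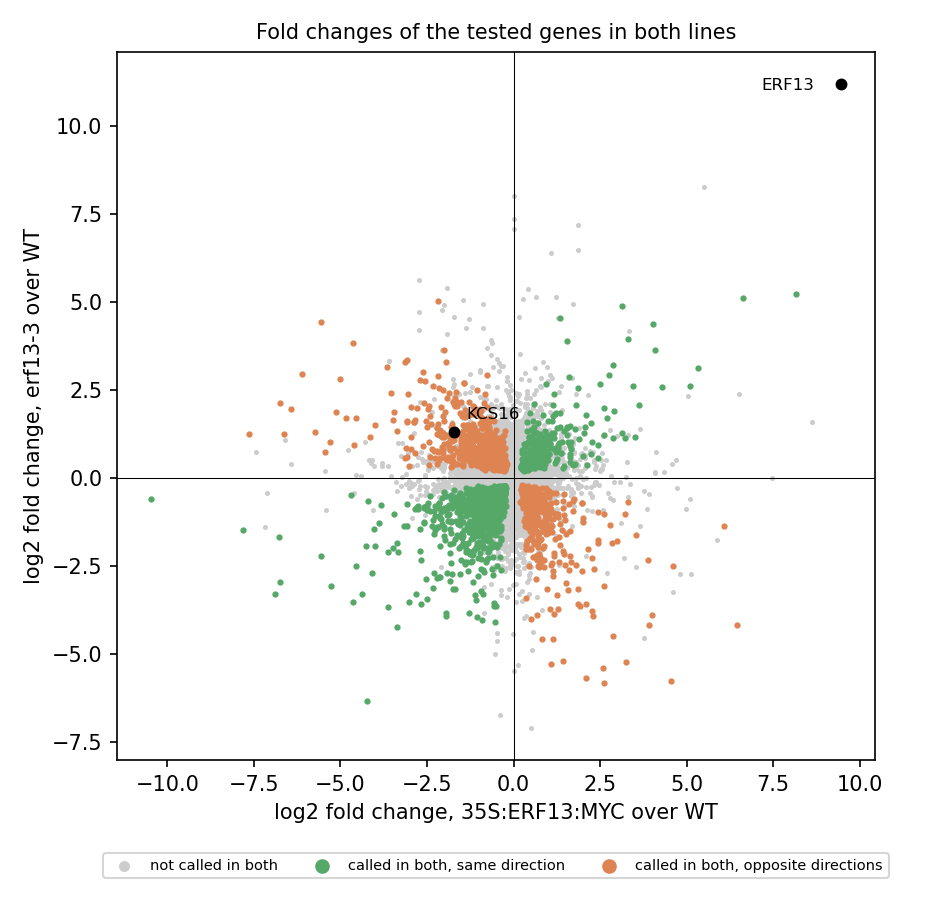
Log2 fold changes of the 19714 tested genes in 35S:ERF13:MYC over WT (x axis) and erf13-3 over WT (y axis), with genes called in both lines coloured by whether they changed in the same (1489) or opposite (1017) directions. KCS16 lies among the opposite changes and ERF13 at the upper right.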

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

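With the alternatives for a named gene, 3359 of 3400 values kept direction and side of the threshold, 41 were no longer past it and none changed direction. Most named genes were picked from the main fit for large or well-supported changes, so this does not describe calls in general. Of 1586 list values, 1494 kept direction and side of the threshold, 50 were no longer past it and 42 newly passed it. ERF13 stayed called in every alternative that tested it, with log2 fold changes of 8.63 to 9.59 and 10.39 to 11.34 for the lines. With the correlation between genes estimated from the data, camera called 0 of 26 lists in each comparison, with 1, 3 and 2 lists at an unadjusted p under 0.05 and a lowest adjusted p of 0.15, 0.056 and 0.45. fry, which does not compare a list with other genes, called 12, 13 and 11, not all of them the same lists. It did not call phosphate starvation in either line (adjusted p = 0.096 and 0.2) or nitrate in erf13-3 (0.056), and it newly called clock, hypoxia and VLCFA elongation for 35S:ERF13:MYC (0.025 each), clock (0.032) and heat shock (0.031) for erf13-3, and cell wall loosening (0.046), heat shock (0.015) and suberin (0.026) for erf13-3 against 35S:ERF13:MYC. Counts of genes depend on the threshold by construction. At an adjusted p under 0.01 there were 3312 genes for 35S:ERF13:MYC, 3310 for erf13-3, 7 lists for erf13-3, and 1160 genes called in both lines, 673 in the same and 487 in opposite directions. With a 2-fold change required there were 1429, 1603 and 2623 genes, and 3, 5 and 2 lists with a median of at least 2-fold. Of 450 genes then called in both, 218 changed in the same and 232 in opposite directions, so like changes no longer outnumber opposite ones. Without a low-count filter the correlation of fold changes was 0.23 (jackknife SE of the main value 0.095); the cause was not tested. Leaving out 1 library gave 3903 to 6725 genes for 35S:ERF13:MYC, 1663 to 2704 genes called in both lines and 969 to 1927 of these in the same direction. Of 6209 genes called for 35S:ERF13:MYC, 4665 were also called without WT replicate 3, and 4651 of 5381 for erf13-3. Leaving out WT replicate 3, 35S:ERF13:MYC replicate 1 and erf13-3 replicate 3 together, chosen after seeing the data, gave 6535, 6325 and 8249 genes and moved no such count by over 1.5 times. It lost the suberin and xylem lists for erf13-3 (adjusted p = 0.056 each), and newly called clock for 35S:ERF13:MYC (0.036), heat shock (0.027) and indole glucosinolate and camalexin (0.014) for erf13-3, and phosphate starvation (0.021) and suberin (0.041) for erf13-3 against 35S:ERF13:MYC. With the replicate number as a block the counts were 6523, 5494 and 8008 genes, 12, 14 and 8 lists, 2685 genes called in both lines, 1603 in the same and 1082 in opposite directions, a correlation of 0.04, and ERF13 log2 fold changes of 9.45 and 11.18. It newly called the cell wall loosening and nitrate lists for 35S:ERF13:MYC (adjusted p = 0.041 each) and root hair for erf13-3 (0.029). The block on erf13-3 and WT alone called 7200 genes and 15 lists, root hair (0.026) and indole glucosinolate and camalexin (0.048) newly among them. The block changed no other list call and no call of a named gene. With 3 libraries per group at this depth, the self-test recovered 39% to 52% of 1.5-fold changes; depth and number of libraries were not varied.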

Other observations

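The tests of the Casparian strip pattern were chosen after its counts were seen, and the process terms were not part of the planned analysis. Process terms in the reference annotation were tested for enrichment among genes changed at least 2-fold (hypergeometric test, one-sided, adjusted over 261 terms, background of 9165 tested genes with a term). Photosynthesis and lipid transport were enriched in opposite directions in the lines. Photosynthesis held 15 of 59 genes among those lower in 35S:ERF13:MYC (3.1 expected, adjusted p = 3.1e-05), 15 of 59 among those higher in erf13-3 (2.59 expected, adjusted p = 5.9e-06) and 31 of 59 among those higher in erf13-3 than in 35S:ERF13:MYC (5.08 expected, adjusted p = 7.7e-16). Lipid transport held 16 of 54 genes among those lower in 35S:ERF13:MYC (2.83 expected, adjusted p = 2.2e-06) and 13 of 54 among those higher in erf13-3 (2.37 expected, adjusted p = 5.1e-05), and 21 of 54 among those higher in erf13-3 than in 35S:ERF13:MYC (4.65 expected, adjusted p = 9.7e-08). Defence response terms were enriched among both the higher genes of 35S:ERF13:MYC, with 22 of 234 (5.23 expected, adjusted p = 2.8e-06), and its lower genes, with 29 of 234 (12.3 expected, adjusted p = 0.0011). Among genes lower in erf13-3, response to water deprivation held 16 of 69 (2.97 expected, adjusted p = 6.4e-06) and response to karrikin 11 of 64 (2.76 expected, adjusted p = 0.0068). Genes are not independent, and these terms share members. The photosynthesis term comes from the same libraries as the green tissue list and is no separate support for it. In 35S:ERF13:MYC replicate 1 that list stood at 0.02, within the WT range. Shoot material in the root samples, which stays open for that list, could move photosynthesis genes too. Whether it also moved lipid transport genes was not tested.

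Genes changed in the same direction by at least 2-fold lay next to each other more often than chance. Among 18629 neighbouring pairs of tested genes whose proteins are not alike (local alignment score under 0.2 of the smaller self score, Biopython 1.88), 256 pairs differed alike between the lines, against a mean of 173 and a highest of 220 in 1000 random reassignments of the calls. The counts were 101 pairs for 35S:ERF13:MYC against WT (random mean 57, highest 81) and 100 for erf13-3 against WT (random mean 62.1, highest 93). The one-sided permutation p of 0.001 is the smallest that 1000 reassignments can give. A candidate explanation is that neighbouring genes are regulated together. Reads shared across overlapping neighbours could also give such pairs and were not tested.

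Green tissue genes fell in 35S:ERF13:MYC and rose in erf13-3, where the root samples may have held less or more shoot material. Of 23 shoot epidermis and leaf polarity markers fixed before this test, 11 were measured, at 1.13 to 48.3 FPKM in WT roots, LTP2 being the most abundant. All 11 were epidermis or cuticle genes, none was a leaf polarity marker, and the other markers were not among the tested genes. CER6 and FDH, both measured, also belong to the VLCFA elongation list. The 11 markers had a median log2 fold change of -0.46 in 35S:ERF13:MYC (95% bootstrap interval -0.81 to 0.41), against -0.83 for the green tissue list. In erf13-3 their median was 0.41 (0.23 to 0.73), against 1.13. The bootstrap resampled genes, so these intervals hold no spread between libraries. Of the 11, 2 were called higher and 5 lower in 35S:ERF13:MYC, and 7 higher and 1 lower in erf13-3. Given outside the rule for named genes, ATML1 stood at -1.39 and 1.72 in the lines and PDF1 at -0.81 and 1.61, but LTP2 at 0.86 and -0.55. Both gaps had been set as evidence against shoot material, but WT roots themselves express these markers at a median of 5.3 FPKM, most of the called ones moved with the green list, and shoot tissue cannot be told apart from a change within roots.

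Of 18 phosphate starvation genes, 14 were called lower in 35S:ERF13:MYC, and 10 lower and 1 higher in erf13-3, and WT replicate 3 held the highest values, which may make a difference that belongs to a single WT library. Without it, 11 of 14 lower calls were kept in 35S:ERF13:MYC, and the list's median log2 fold change was -0.77, which argues against that library as the whole cause in this line, though the list's call (adjusted p = 1.7e-05 without it) held only at the preset correlation (on all libraries adjusted p = 0.73 with an estimated correlation, and 0.096 by fry). The bounds set beforehand were that at least 2 of 3 of the calls and 0.5 of the median be kept. The share of the median kept was 0.51, just above its bound. The 95% bootstrap interval of that share, from resampling genes and not libraries, was 0.24 to 0.73. Part of the size may therefore come from WT replicate 3. In erf13-3, 8 of 10 lower calls were kept and the higher ones went from 1 to 3, but the median was -0.3 and kept 0.27 of its size, under the bound set for the library as the cause, and the list was no longer called (adjusted p = 0.12; on all libraries adjusted p = 0.63 with an estimated correlation, and 0.2 by fry). The interval of that share, -0.31 to 0.6, spans the bound, the list was called with WT replicate 3, 35S:ERF13:MYC replicate 1 and erf13-3 replicate 3 all left out (adjusted p = 0.036), and an effect of the genotype remains open.

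Casparian strip genes fell in 35S:ERF13:MYC and rose in erf13-3. A larger share of all differentiated root tissue in erf13-3 would raise suberin and xylem genes too. Those genes had 0 called higher and 13 called lower, against 6 and 0 for the Casparian strip. Fisher's exact test, which takes genes as independent, gave a two-sided p of 3.7e-05. The test and its lists were chosen after the counts were seen, so this p describes the counts and gives no support of its own. The list means per library lay above WT for the Casparian strip (0.28 to 0.53 against -0.2 to 0.18). They lay below it for suberin (-0.3 to -0.21 against -0.15 to 0.17) and xylem (-0.47 to -0.27 against -0.2 to 0.19). These list means argue against such a larger share, unless the genotype itself lowers suberin and xylem genes, which was not tested. The suberin and xylem falls also rested in part on WT replicate 3. Without that library camera called neither list (adjusted p = 0.093 each). Suberin then had 1 member higher and 6 lower, with a median log2 fold change of 0.01, and xylem 0 higher and 5 lower. Root hair genes moved with the Casparian strip, with 6 higher and 1 lower (Fisher's exact test, two-sided p = 0.004 with these counted among the others), so a larger share of only some differentiated tissue stays open. In 35S:ERF13:MYC, suberin, root hair and xylem genes had 0 called higher and 27 lower, against 0 and 10, and Fisher's exact test has a p of 1 by construction and decides nothing. A smaller share of differentiated tissue in that line cannot be told apart from an effect of the genotype on these genes themselves.

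Libraries of a group also differed along gene length. The Spearman correlation across genes between a library's deviation from its group mean and gene length was -0.26 in WT replicate 3, -0.19 in 35S:ERF13:MYC replicate 1 and -0.31 in erf13-3 replicate 3, and between 0.1 and 0.28 in the other 6 libraries. Across genes, the deviations of WT replicate 3 correlated with those of erf13-3 replicate 3 (r = 0.44) and 35S:ERF13:MYC replicate 1 (r = 0.31), and the last pair had r = 0.24.

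Each comparison has 10 splits of its 6 libraries, too few for a share under 0.05. Every split but the real one mixes both genotypes in each group, so a genotype effect widens the spread within groups. The counts of those splits are therefore not a level of calls by chance. In fits on the 2 genotypes alone, edgeR called 5894 genes for 35S:ERF13:MYC against WT, 4491 for erf13-3 against WT and 8272 for erf13-3 against 35S:ERF13:MYC. The highest count of the other 9 splits, those that part all 3 same-numbered pairs included, was 0 in each comparison, with 864, 1328 and 798 genes at an unadjusted p under 0.05, and 1 of the 10 splits, the real one, gave as many genes.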
